A study of Rattus norvegicus with 60 samples.

How the data were processed

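RNA from the dorsal and the ventral hippocampus of 30 rats was sequenced as 60 libraries. Per the labels' protocols, regions were punched from 300 µm cryostat sections, 500 ng of total RNA went into a stranded polyA library preparation (Illumina TruSeq), and libraries were sequenced as paired reads of 75 bases on a NextSeq instrument with a target of 25 M reads per sample. The labels also say that the young and the aged animals were sequenced in 2 separate batches.

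The values used are raw counts per gene. Per the submitters' processing notes the tools named are bcl2fastq 2.20.0.422, cutadapt (no version given), FastQC 0.11.8, STAR 2.6.1a and HTSeq 0.11.0, with the genome build Rnor_6.0. The annotation release and the strand setting of the counting are not given in the sources used here, so a gene and an overlapping or antisense neighbour are uncertain, as are genes with near-identical copies, because reads aligned to several places were not counted. Each deposited file holds whole-number counts for 32754 Ensembl gene identifiers and 5 lines for reads assigned to no gene. Those lines were left out of library sizes and tests. Reads in genes were 56.3% to 68.8% of each file's total, reads in no annotated feature 18.3% to 21.6%, reads not aligned 2.88% to 19.3%, reads aligned to several places 6.04% to 8.87% and ambiguous reads 0.107% to 0.153%. The share of aligned reads that aligned to several places was 7.94% to 9.61% in the young batch and 7.20% to 9.01% in the aged batch. A merged table of the same counts was not used here.

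The files do not pair gene identifiers with symbols. The reference table at hand (assembly GRCr8, 47357 rows) pairs none of its rows with an Ensembl identifier, so 0 of the 32754 identifiers were matched, and no positions are given. The 35 gene lists set before the data were examined, the set tests on them, and the covariate built from 1 of them could therefore not be run. The rule for named genes, also set before the data were examined, asked for the genes with a symbol that passed the test, had a mean log2 CPM of at least 1 and changed most. It was applied to identifiers in place of symbols and shortened to at most 2 genes that rose and 2 that fell in each comparison. The level minimum was dropped where fewer than 20 genes passed. Where none passed, the genes with the smallest p were picked as not passing, at most 3 in a parity contrast and 2 in a test with 2 degrees of freedom. Only some of these are named below.

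Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with robust dispersion estimates, TMM normalization, the filterByExpr filter at its default minimum count of 10, and Benjamini-Hochberg adjustment at a threshold of 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Regional differences and their interactions with age and parity came from a fit to all 60 libraries with a term for each animal and a dorsal-minus-ventral term for each of the 6 age and parity groups. Age was tested within each region on 30 libraries with 6 group means, and parity within each age and region on 15 libraries with 3 group means. This gave 22 comparisons. Levels are given as CPM, counts relative to the library total after TMM, and log2 CPM with a prior count of 2.

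Replicates are separate animals per the labels. The animal numbers in the labels pair the dorsal and ventral libraries. The deviations of an animal's 2 libraries from their group means correlated across genes, which are not independent replicates, at a median r of 0.29 (lowest 0.16, highest 0.45), against a median of -0.02 between different animals of the same age. Over all genes, 24 of 30 dorsal libraries correlated best with the ventral library of their own animal. On 77 and 48 genes whose deviations agreed between regions in the other age, 15 of 15 young and 15 of 15 aged dorsal libraries did so. Within groups no libraries agreed within sampling noise, since the lowest chi-square per degree of freedom between replicates was 4.79.

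The fits were tested on simulated data, drawn from the means, dispersions and library sizes of the real libraries with 50 genes changed at each of 4 folds. Each gene was drawn independently. With many changed genes the adjusted threshold is easier to pass, so recovery could be lower where only a few genes change. For dorsal against ventral over all animals (14689 genes), 90% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered. For aged against young, 84% of genes changed 1.5-fold and 96% of those changed 2-fold were recovered in the dorsal hippocampus (14305 genes), and 84% and 92% in the ventral hippocampus (14445 genes). In the young ventral hippocampus (14384 genes), 70% and 82% were recovered for primiparous against nulliparous animals. There, 46% of genes changed 1.25-fold were recovered.

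Depth ranged from 13.9 to 97.9 M counts in genes. The most abundant gene held 0.843% to 2.64% of the counts of a library. Genes detected were compared after random thinning of each library to 13 M counts, which gave 14915 to 16389 genes. Alternatives set before the data were examined were RLE size factors, no low-count filter beyond 1 count, DESeq2 1.42.0, leaving out each animal, no replicate block for the regional tests, nulliparous animals only for age, and a single fit over all libraries for parity. Alternatives chosen after seeing the data were to leave out the 3 animals whose dorsal libraries held the fewest genes, to use the number of genes as a covariate, and to use only libraries of under 35 M counts. Groups were also exchanged at random among the same samples, 24 times for the tests with the animal as a block and 99 times for the others, and for the tests of age and of age by parity that number was raised after a first run had been seen.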

Results

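Gene expression was measured by sequencing of polyadenylated RNA from the dorsal and ventral hippocampus of 30 female Sprague-Dawley rats, an outbred laboratory strain. The animals were nulliparous (never pregnant), primiparous (1 litter) or biparous (2 litters), and were killed at 7 months, which for the mothers was 30 days after birth, or at 13 months, which was more than 6 months after birth. Each of the 12 combinations of age, parity and region held 5 libraries, 60 in all, and each animal gave 1 dorsal and 1 ventral library. The dorsal and ventral hippocampus differ in their connections and are commonly linked to spatial memory and to stress and anxiety, respectively. Libraries held between 13.9 and 97.9 M (mega) counts in genes. The young libraries ranged from 13.9 to 97.9 M (median 24.3 M) and the aged libraries from 15.1 to 29.5 M (median 20.9 M). Of the young libraries, 10 held more than 35 M counts, and none of the aged libraries did. The young and the aged animals were sequenced in 2 separate batches, so that age and batch are the same split of the libraries.

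**Figure D1:**
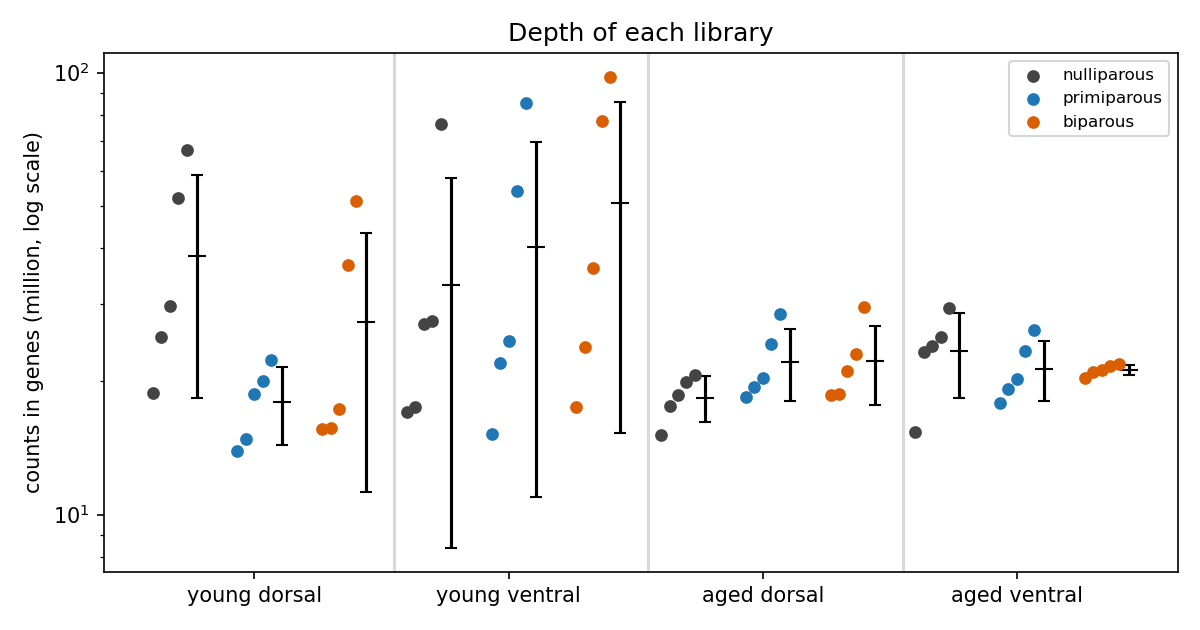
Counts in genes per library in M (vertical axis, log scale) for the 12 groups, coloured by parity. Each point is 1 library, and the bar to the right of each group gives the mean and SD of its 5 libraries. The young libraries spread from 13.9 to 97.9 M and the aged libraries from 15.1 to 29.5 M.

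The files name genes by Ensembl rat identifiers and do not pair them with gene symbols, and none of the 32754 identifiers could be matched to a symbol. Genes are therefore given by identifier, with at most 2 that rose and 2 that fell in a comparison, and without a position or function. Where many genes passed, the named genes are those with the largest changes among passing genes with a mean log2 CPM of at least 1.

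The first comparison asked which genes differ between the dorsal and the ventral hippocampus of the same animal. Averaged over all 30 animals, 3683 genes were higher in the dorsal and 3974 were higher in the ventral hippocampus, 52.1% of the 14689 genes tested. Most of these differences were small. The median absolute log2 fold change of the passing genes was 0.18, and 208 genes were more than 2-fold higher and 177 more than 2-fold lower in the dorsal hippocampus. The largest rise was that of ENSRNOG00000016275, at a log2 fold change of 6.48 (SE 0.79, adjusted p = 1.35e-07), with a mean of 374 ± 556 CPM (counts relative to the library total) in dorsal and 12.9 ± 52.1 CPM in ventral libraries (SD, n = 30 each). ENSRNOG00000005770 followed at 5.04 (SE 0.69, adjusted p = 1.21e-06), with 5.28 ± 7.83 CPM in dorsal and 0.244 ± 0.955 CPM in ventral libraries (SD, n = 30 each). Both were uneven between animals. ENSRNOG00000016275 was higher in the dorsal library in 27 of 30 animals and ENSRNOG00000005770 in 22 of 30, and the dorsal libraries spanned log2 CPM values from -3.82 to 10.8 for the former.

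The largest falls were far more even. ENSRNOG00000028774 had a log2 fold change of -4.70 (SE 0.12, adjusted p = 3.37e-27), from 7.14 ± 2.47 CPM in ventral to 0.294 ± 0.182 CPM in dorsal libraries (SD, n = 30 each). ENSRNOG00000001959 had -2.94 (SE 0.16, adjusted p = 1.83e-14), from 12.1 ± 3.38 to 1.69 ± 1.13 CPM (SD, n = 30 each). Both were lower in the dorsal library in 30 of 30 animals. These adjusted p-values come from the quasi-likelihood test of edgeR with the animal as a block and Benjamini-Hochberg adjustment.

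**Figure D2:**
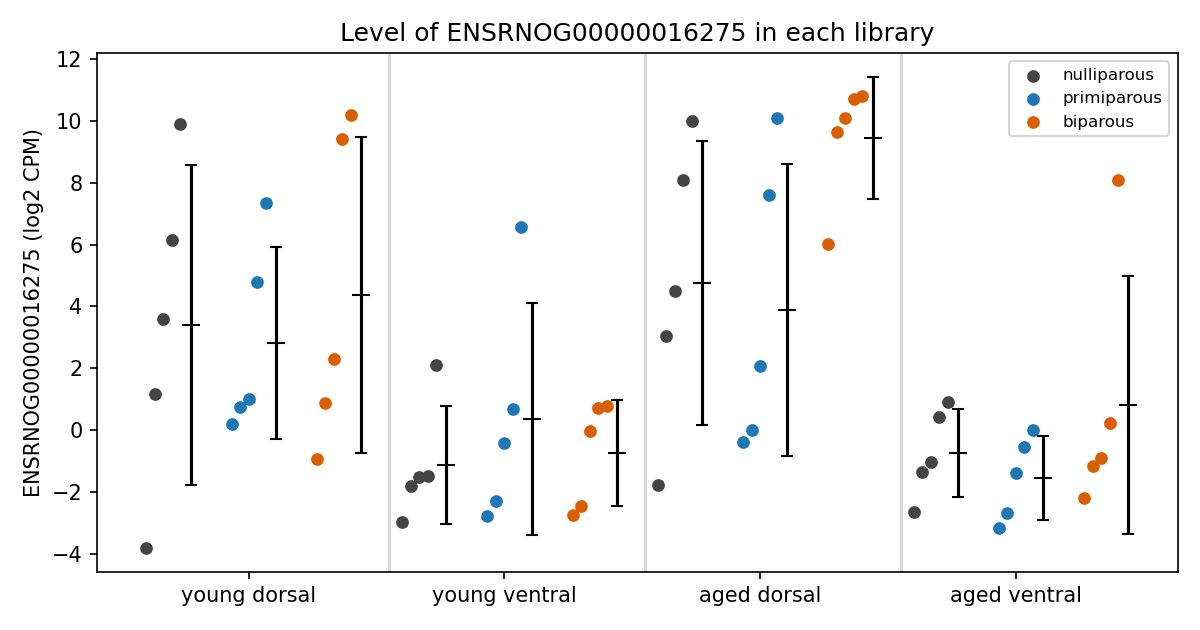
Level of ENSRNOG00000016275, the gene with the largest dorsal excess, in log2 CPM (vertical axis) in each library, by age, region and parity. Each point is 1 library, and the bar to the right of each group gives the mean and SD of its 5 libraries. Dorsal libraries spread from -3.82 to 10.8 and ventral libraries from -3.17 to 8.10.

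A set of 56 further genes moved with ENSRNOG00000016275 between dorsal libraries. They were 56 of the 208 genes more than 2-fold higher in the dorsal hippocampus, and their deviations from the group means followed those of ENSRNOG00000016275 with a Pearson r above 0.6 over the 30 dorsal libraries. Among 200 shuffles of the libraries within groups the highest such count was 4. The mean level of the set spanned log2 CPM values from -2.03 to 2.48 in dorsal libraries and from -2.06 to 0.44 in ventral libraries. Of the 177 genes more than 2-fold lower in the dorsal hippocampus, 1 followed ENSRNOG00000016275 in this way. These genes were chosen for a lower dorsal level, such as ENSRNOG00000028774 at a mean of 0.294 CPM, which can limit how far they vary there. The 1 and the 56 are therefore not like counts.

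The regional difference was also tested within each age. In the young animals 3211 genes were higher and 3197 lower in the dorsal hippocampus, and in the aged animals 3432 were higher and 3746 lower. Of the genes passing in both ages, 1954 were higher in dorsal in both, where independent lists would share 750, and 1813 were lower in both, where independent lists would share 815. A further 427 genes passed in both ages with opposite signs. Across genes, which are not independent replicates, the log2 fold changes of the 2 ages had a Pearson r of 0.80 and a Spearman rho of 0.54. The 4 genes named above had the largest changes at each age too. The log2 fold change of ENSRNOG00000016275 was 4.91 (SE 1.08) in the young and 8.05 (SE 1.15) in the aged animals, with adjusted p-values of 5.89e-04 and 2.18e-06. ENSRNOG00000028774 had log2 fold changes of -4.73 (SE 0.17) and -4.66 (SE 0.17), with adjusted p-values of 4.78e-22 and 3.51e-22.

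Whether the regional difference itself changed with age was tested as the aged minus the young dorsal-to-ventral difference. The dorsal-to-ventral ratio was higher in aged than in young animals for 1289 genes and lower for 1967 genes, 22.2% of the genes tested. The regional difference was larger in the aged animals for 1997 of these 3256 genes and larger in the young animals for 1259. The changes were small, with a median absolute log2 change of 0.22, and 51 genes changed more than 2-fold. ENSRNOG00000016275, at log2 fold changes of 4.91 in young and 8.05 in aged animals, was not among the passing genes. Among passing genes with a mean log2 CPM of at least 1, the ratio rose most for ENSRNOG00000018735 (log2 change 1.22, SE 0.22, adjusted p = 2.88e-04). This gene had 10.1 ± 6.87 CPM in young dorsal, 13.3 ± 9.97 in young ventral, 15.5 ± 6.22 in aged dorsal and 8.87 ± 4.10 CPM in aged ventral libraries (SD, n = 15 each). ENSRNOG00000032844 rose by 1.17 (SE 0.26, adjusted p = 1.32e-03), and without the animal as a block it no longer passed (log2 change 1.21, edgeR adjusted p = 0.0513). At that level the ratio fell most for ENSRNOG00000031053 (log2 change -1.42, SE 0.23, adjusted p = 1.06e-04). It went from 225 ± 80.9 CPM in young dorsal and 161 ± 52.4 in young ventral libraries to 107 ± 31.5 in aged dorsal and 241 ± 149 CPM in aged ventral libraries (SD, n = 15 each). ENSRNOG00000052406 followed at -1.33 (SE 0.19, adjusted p = 2.00e-05). The difference of each aged animal lay beyond the young mean in the direction of the change in 14 of 15 aged animals for the first pair and in 15 of 15 for the second pair. The test was edgeR's quasi-likelihood test with the animal as a block, and without the block 287 genes were higher and 1301 lower. A batch effect that multiplies a gene alike in both regions cancels in this comparison, but a batch effect that differs between regions does not.

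**Figure D3:**
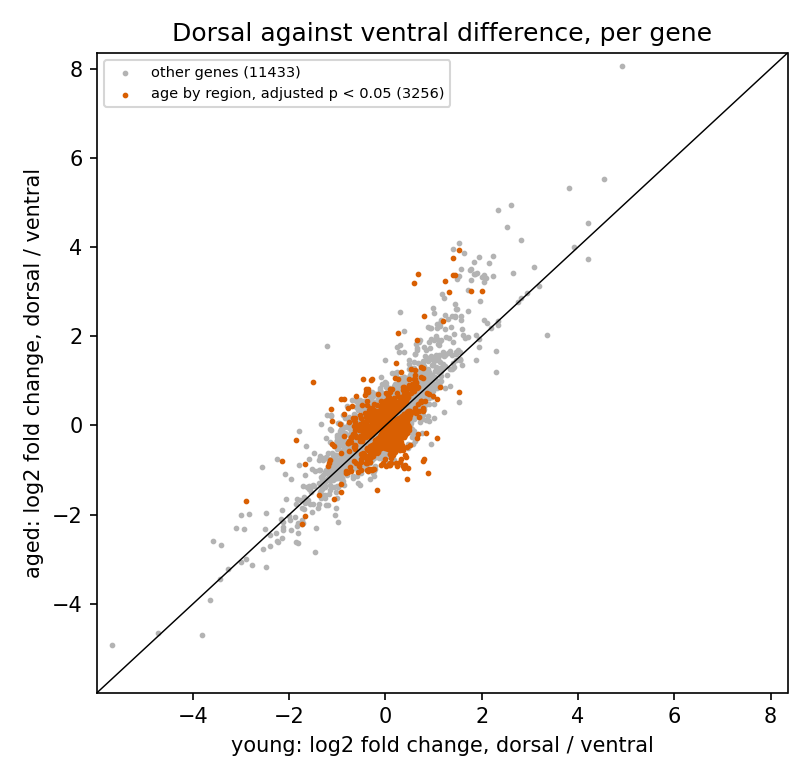
Log2 fold change of dorsal over ventral for each of 14689 genes in young (horizontal axis) and aged animals (vertical axis). Each point is 1 gene, the line marks equal values, and the 3256 genes whose regional difference changed with age at an adjusted p under 0.05 are in orange.

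Aged animals were then compared with young animals within each region. In the dorsal hippocampus 2481 genes were higher and 2730 lower in aged animals, of 14305 tested, and in the ventral hippocampus 4277 were higher and 4191 lower, of 14445 tested. Larger changes were mostly falls. In the dorsal hippocampus 24 genes were more than 2-fold higher and 131 more than 2-fold lower in aged animals, and in the ventral hippocampus 36 were higher and 240 lower by that margin. Among passing genes with a mean log2 CPM of at least 1, ENSRNOG00000055936 fell most in both regions. It had a log2 fold change of -2.21 (SE 0.15, adjusted p = 1.43e-11) in dorsal libraries, from 11.3 ± 2.21 to 2.46 ± 1.12 CPM, and of -2.37 (SE 0.20, adjusted p = 3.83e-10) in ventral libraries, from 9.23 ± 1.96 to 1.81 ± 1.05 CPM (SD, n = 15 each). ENSRNOG00000017463 followed with -2.17 (SE 0.16, adjusted p = 1.67e-11) and -2.34 (SE 0.19, adjusted p = 1.93e-10). Both were below the young mean in 15 of 15 aged animals in each region. In the ventral hippocampus the largest rises at that level were those of ENSRNOG00000058908 (1.63, SE 0.20, adjusted p = 1.06e-07), from 2.03 ± 0.74 to 6.28 ± 2.41 CPM, and ENSRNOG00000039759 (1.26, SE 0.17, adjusted p = 4.93e-07), from 6.11 ± 1.67 to 14.7 ± 5.30 CPM (SD, n = 15 each).

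In the dorsal hippocampus the largest rises among passing genes with a mean log2 CPM of at least 1 were those of ENSRNOG00000058105 (1.51, SE 0.19, adjusted p = 9.89e-07) and ENSRNOG00000029886 (1.43, SE 0.22, adjusted p = 1.75e-05). They had 19.5 ± 17.7 and 35.3 ± 31.4 CPM in young and 41.4 ± 9.60 and 71.0 ± 17.5 CPM in aged libraries (SD, n = 15 each). These 2 rises were not seen in nulliparous animals, where the log2 differences between aged and young were -0.18 and -0.13, with adjusted p-values of 0.621 and 0.738. Of the genes passing in both regions, 2020 were higher and 2224 lower in aged animals in both, against 744 and 792 for independent lists, and 78 passed with opposite signs. The 2 regions came from the same animals and were sequenced in the same batches. With nulliparous animals alone, 2032 genes passed in the dorsal and 5148 in the ventral hippocampus. All of these counts are from edgeR's quasi-likelihood test, and since each age was sequenced as its own batch, age and batch cannot be told apart in them. Among the mothers, time since birth also differed with age, at 30 days in the young and more than 6 months in the aged animals.

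The effect of parity was tested within each age and region, 5 animals against 5. In the young dorsal hippocampus 267 genes were higher and 102 lower in biparous than in primiparous animals, of 14031 tested with edgeR's quasi-likelihood test. Their median absolute log2 fold change was 0.32, and 7 of the 369 genes changed more than 2-fold. Over all 369 genes the log2 fold changes ran from -1.64 to 1.34. Among those with a mean log2 CPM of at least 1, ENSRNOG00000029707 rose most (log2 fold change 1.30, SE 0.18, adjusted p = 0.0260). It went from 29.9 ± 5.57 CPM in primiparous to 73.2 ± 17.3 CPM in biparous animals, with 42.9 ± 5.53 CPM in nulliparous animals (SD, n = 5 each). ENSRNOG00000031053, which also led the named falls in the test of age by region, rose by 1.07 (SE 0.19, adjusted p = 0.0315), from 135 ± 24.6 to 281 ± 65.1 CPM, with 260 ± 49.2 CPM in nulliparous animals. ENSRNOG00000045924 fell by 0.99 (SE 0.23, adjusted p = 0.0404), from 4.37 ± 0.915 to 2.16 ± 0.599 CPM, and ENSRNOG00000005729 fell by 0.52 (SE 0.09, adjusted p = 0.0260), from 20.3 ± 1.92 to 14.2 ± 1.54 CPM (SD, n = 5 each). Each of the 4 lay beyond the primiparous mean in 5 of 5 biparous animals. DESeq2 called 666 higher and 537 lower, a single fit over all libraries 504 higher and 495 lower, and with only the 11 libraries under 35 M counts no gene passed with edgeR (2411 with an unadjusted p under 0.05). With those 11 libraries the median log2 fold change of the 369 genes was 0.30. The libraries left out were those of biparous animals 55 and 71 and nulliparous animals 41 and 61. The loss of calls can therefore also come from the smaller groups. Depth was uneven between the young dorsal groups, at 13.9 to 22.4 M counts in primiparous, 15.6 to 51.2 M in biparous and 18.8 to 66.8 M in nulliparous libraries. In the single fit ENSRNOG00000031053 and ENSRNOG00000045924 no longer passed (edgeR adjusted p = 0.0694 and 0.0940), at log2 fold changes of 1.06 and -0.99. The count depended strongly on which animals were included. It was 0 without animal 13, 26, 55, 68 or 71, 1 without animal 50, 3 without animal 66, 31 without animal 21, 182 without animal 29, 207 without animal 42, 889 without animal 54 and 1334 without animal 3.

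The number of genes detected at equal depth was compared between the young dorsal groups, and no difference passed after adjustment. After thinning to 13 M counts, primiparous libraries held 16150 ± 131 genes, nulliparous libraries 15737 ± 430 and biparous libraries 15618 ± 477 (SD, n = 5 each). The difference in means was 412.4 genes for primiparous minus nulliparous (exact permutation p = 0.0238, adjusted 0.0596), -531.8 for biparous minus primiparous (exact permutation p = 0.0397, adjusted 0.0596) and -119.4 for biparous minus nulliparous (exact permutation p = 0.651, adjusted 0.651), two-sided, with Benjamini-Hochberg adjustment over the 3 comparisons. The 3 lowest of all 60 libraries were the dorsal libraries of animals 55 (biparous, 51.2 M counts), 68 (biparous, 15.6 M) and 61 (nulliparous, 66.8 M). Without these 3 animals, or with the number of genes as a covariate, no gene passed between biparous and primiparous animals with edgeR, while 1808 and 1340 genes had an unadjusted p under 0.05. All 369 genes kept their direction in both settings, and their median log2 fold change went from 0.32 (median SE 0.08) to 0.26 (median SE 0.08) without the 3 animals and to 0.24 (median SE 0.09) with the covariate. The 369 were picked for passing in these same libraries, so keeping their direction was likely in advance.

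Between primiparous and nulliparous young animals no gene passed in the dorsal hippocampus with edgeR, and DESeq2 called 176. With edgeR 1917 of 14031 had an unadjusted p under 0.05, where chance would give 702 on average in each young dorsal contrast. Genes are not independent replicates, so such a count can lie far from this average by chance. The spread of these counts was not measured, here or in the contrasts below. A single edgeR fit over all libraries called 18. Without animal 54 the edgeR count was 17 and without animal 59 it was 3. The 3 smallest p-values belonged to ENSRNOG00000019587, with 894 ± 55.6 CPM in primiparous and 751 ± 34.3 CPM in nulliparous animals, ENSRNOG00000008039, with 27.2 ± 3.12 and 37.9 ± 3.04 CPM, and ENSRNOG00000013312, with 33.1 ± 2.09 and 43.0 ± 1.84 CPM (SD, n = 5 each, edgeR adjusted p = 0.115 for all 3). In simulated counts for this comparison, 60% of genes changed 1.5-fold, 86% changed 2-fold and 90% changed 4-fold were recovered. These shares hold for 50 genes changed at each of 4 folds and could be lower where only a few genes change. Between biparous and nulliparous young animals 1 gene passed, ENSRNOG00000002194, which fell by 0.41 on the log2 scale (SE 0.06, edgeR adjusted p = 0.0362), from 62.4 ± 3.90 to 46.9 ± 3.27 CPM (SD, n = 5 each), below the nulliparous mean in 5 of 5 biparous animals. It no longer passed without animal 21, 26, 29, 41, 42, 50, 55, 59, 61, 66 or 68, the count was 2 without animal 3, and 783 genes had an unadjusted p under 0.05. DESeq2 called 6 genes and a single edgeR fit over all libraries 34 (13 higher, 21 lower), while without animals 55, 61 and 68, and with only libraries under 35 M counts, no gene passed with edgeR (701 and 716 with an unadjusted p under 0.05). The log2 fold change of ENSRNOG00000002194 was -0.32 and -0.43 in these settings, which compare fewer animals.

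In the young ventral hippocampus 1 gene passed in 1 of the 3 parity contrasts. ENSRNOG00000045989 was lower in biparous than in nulliparous animals (log2 fold change -2.97, SE 0.45, edgeR adjusted p = 0.0345), at 0.265 ± 0.132 against 1.91 ± 0.754 CPM (SD, n = 5 each), and in primiparous animals it had 0.30 ± 0.19 CPM (log2 fold change against nulliparous -2.57, SE 0.43, edgeR adjusted p = 0.155). In this contrast it passed with DESeq2 (adjusted p = 2.40e-04) and in the single edgeR fit over all libraries (adjusted p = 0.0195). It lay below the nulliparous mean in 5 of 5 primiparous animals. In aged ventral libraries it had 0.998 ± 0.22 (nulliparous), 1.01 ± 0.52 (primiparous) and 0.469 ± 0.288 CPM (biparous, SD, n = 5 each). The genes with the smallest p in the tests of age by parity, described below, were also lower in young mothers. Whether ENSRNOG00000045989 moved with those genes was not tested, so it is not shown to be a separate effect of parity. Between biparous and nulliparous animals DESeq2 called 9 genes and the single fit 6, and 318 had an unadjusted p under 0.05 with edgeR. Chance would give 719 such genes on average in each of the 3 young ventral contrasts. No gene passed with edgeR between primiparous and nulliparous animals (446 with an unadjusted p under 0.05, 7 called by DESeq2, 6 in the single fit) or between biparous and primiparous animals (350 with an unadjusted p under 0.05, 0 called by DESeq2). The call for biparous animals was lost without animal 3, 13, 21, 41, 42, 50, 55, 59, 66 or 71, that count was 2 without animal 54 or 68, and 1 gene passed between primiparous and nulliparous animals without animal 61.

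In the aged animals no gene passed in any of the 6 parity contrasts with edgeR or with DESeq2. The numbers of genes with an unadjusted p under 0.05 were 479 (primiparous against nulliparous), 713 (biparous against nulliparous) and 417 (biparous against primiparous) of 13917 in the dorsal hippocampus, where chance would give 696 on average. They were 364, 597 and 280 of 13956 in the ventral hippocampus, where chance would give 698 on average. In simulated counts for primiparous against nulliparous aged animals, 74% of genes changed 1.5-fold and 86% of genes changed 2-fold were recovered in the dorsal hippocampus, and 68% and 86% in the ventral hippocampus.

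Whether the regional difference depended on parity was tested across the 3 parity groups at each age. In the young animals 3 of 14689 genes passed edgeR's 2-degree-of-freedom test, ENSRNOG00000001238, ENSRNOG00000006432 and ENSRNOG00000007351, each with an adjusted p of 0.0329, while 2172 had an unadjusted p under 0.05. DESeq2 called 23 genes, 1 of these 3 among them. They are named because so few passed, after their values were seen. In all 3 the dorsal level was below the ventral level in primiparous animals and above it in the others. The dorsal minus ventral log2 differences of ENSRNOG00000006432 were -0.29 ± 0.21 in primiparous, 0.14 ± 0.07 in nulliparous and 0.37 ± 0.23 in biparous animals (SD, n = 5 each). Those of ENSRNOG00000001238 were -0.12 ± 0.06, 0.09 ± 0.09 and 0.27 ± 0.11, and those of ENSRNOG00000007351 were -0.16 ± 0.18, 0.28 ± 0.14 and 0.35 ± 0.16, in the same order. Without the block, and without animals 55, 61 and 68, no gene passed with edgeR (852 and 1926 with an unadjusted p under 0.05). The count was also 0 without animal 13, 21, 26, 50, 54, 66 or 68, 1 without animal 29 or 71 and 6 without animal 55. In the aged animals no gene passed with edgeR or DESeq2, and 345 had an unadjusted p under 0.05 with edgeR. Chance would give 734 such genes on average at either age.

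Whether the difference between ages depended on parity was tested in each region. No gene passed in edgeR's 2-degree-of-freedom test in the dorsal hippocampus (1252 with an unadjusted p under 0.05, 2 called by DESeq2) or in the ventral hippocampus (280 with an unadjusted p under 0.05, 5 called by DESeq2). Chance would give 715 dorsal and 722 ventral genes on average with an unadjusted p under 0.05. In dorsal libraries 3 genes passed without animal 26 and 1 without animal 29, 54 or 55, and in ventral libraries 4 passed without animal 26, 3 without animal 21 or 54 and 2 without animal 29 or 50. The smallest p-values belonged to ENSRNOG00000058105 and ENSRNOG00000047321 in dorsal libraries (edgeR adjusted p = 0.0785 and 0.470) and to ENSRNOG00000029886 and ENSRNOG00000061299 in ventral libraries (edgeR adjusted p = 0.0749 for both). These 4 genes moved together, with a lowest Pearson r of 0.975 between any pair of them over the 60 libraries. Their mean level in dorsal libraries was 5.24 ± 0.36 log2 CPM in young nulliparous, 2.78 ± 1.3 in young primiparous and 2.71 ± 0.63 in young biparous animals, and 5.04 ± 0.35, 5.21 ± 0.33 and 5.16 ± 0.42 in the aged groups in the same order (SD, n = 5 each). In ventral libraries it was 5.88 ± 0.50, 3.12 ± 1.2 and 3.24 ± 0.66 in the young and 5.18 ± 0.16, 5.28 ± 0.42 and 4.98 ± 0.18 in the aged groups (SD, n = 5 each). The mean of the 4 genes was chosen for this description after its values were seen.

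**Figure D4:**
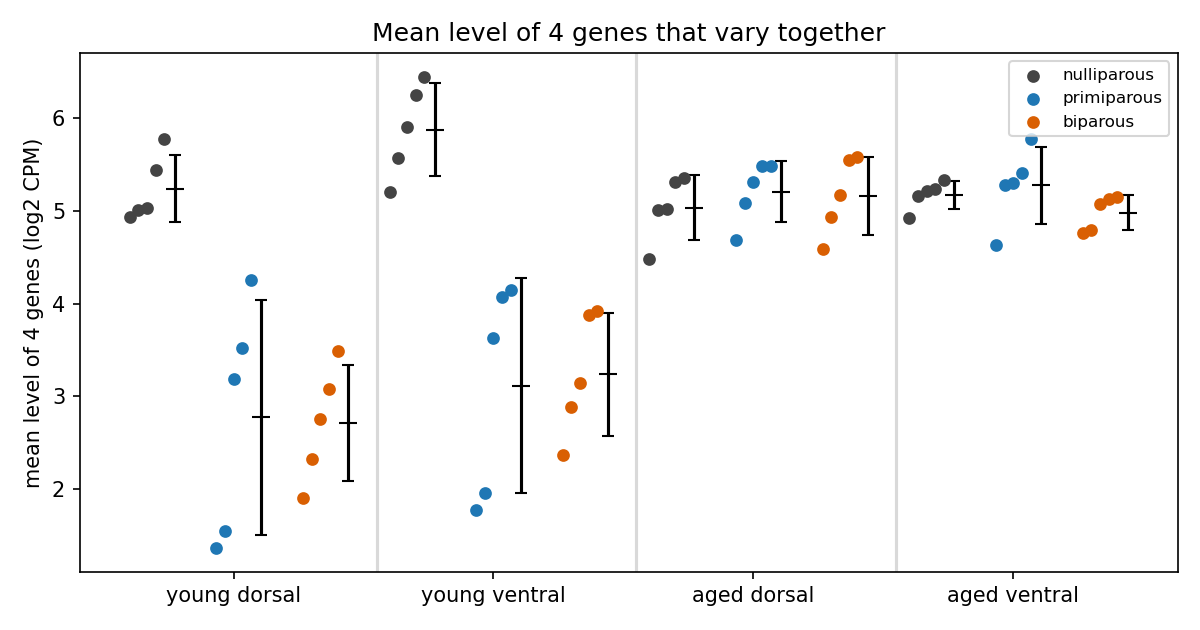
Mean level of the 4 genes with the smallest p in the tests of age by parity, in log2 CPM (vertical axis), in each library by age, region and parity. Each point is 1 library, and the bar to the right of each group gives the mean and SD of its 5 libraries. Young primiparous and biparous libraries lie between 1.36 and 4.25, below all young nulliparous libraries, which lie between 4.94 and 6.45.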

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

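Chosen only after the result was seen were the tests of punch position, depth and RNA of other cells for the 4 genes, the test of a neighbouring tissue in the dorsal punch, the covariate and the depth limit as settings, the allowance for the spread when a value is set against its bound and the way that spread was measured, the reading of splits with a real count of 0 and of the set near its lowest ventral level as deciding nothing, and the final number of regroupings in the tests of age and of age by parity.

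Of 96 groups of 5 values examined, 12 held a sample far from the other 4, where chance gives about 1 in 20 independent groups. These groups are not independent, since 7 of the 12 come from 2 genes named for their large and uneven dorsal excess. The ventral library of young nulliparous animal 42 held 76.3 M counts, against 17.1 to 27.4 M in the rest of its group. At equal depth the ventral library of young biparous animal 68 held 16389 genes, against 16066 to 16138, and the dorsal library of young nulliparous animal 61 held 14992, against 15786 to 16071. The share of reads in genes was 66.4% in the ventral library of aged nulliparous animal 43, against 64.1% to 64.7%, and 67.1% in the dorsal library of young biparous animal 3, against 64.5% to 65.1%. ENSRNOG00000016275 stood at 6.02 log2 CPM in the dorsal library of aged biparous animal 35, against 9.64 to 10.8, and at 8.10 in the ventral library of aged biparous animal 39, against -2.19 to 0.22. ENSRNOG00000005770 stood at 0.35 and 2.39 log2 CPM in the same 2 libraries, against 3.52 to 4.58 and -3.82 to -3.07. It also stood apart in the ventral library of aged nulliparous animal 43 (-1.84, which is 0.208 CPM, against -3.82 in all others, the value of 0 counts), the dorsal library of young primiparous animal 26 (1.34, against -3.11 to -2.23) and the ventral library of young primiparous animal 13 (0.29, against -3.82 to -3.12).

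The first pattern is the set of 56 genes that vary with ENSRNOG00000016275 between dorsal libraries. If the amount of a neighbouring tissue in the dorsal punch varied, the set would vary from punch to punch and not from animal to animal. Over the 30 animals the dorsal and ventral deviations of the set correlated at r = 0.12 (permutation p = 0.544; rho = 0.03, p = 0.894; r = 0.12 without the 2 most distant animals; r = -0.04, p = 0.881 in the young and r = 0.22, p = 0.415 in the aged batch), but the set lay within 1 log2 unit of its lowest ventral value in 27 of 30 ventral libraries, so the correlation would be low under any cause and decides nothing. A varying share of such tissue stays open, and no tissue was tested, because the marker lists could not be matched to identifiers. The 6 age and parity groups held 27.1% of the variance of the set in dorsal libraries (permutation p = 0.156), so a contribution of age or parity stays open.

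The second pattern is the 4 genes that were lower in young mothers. A position that varied by itself in each punch is argued against for the differences between animals within a group. The dorsal and ventral deviations of the 4-gene mean from the group means correlated over the 30 animals at r = 0.92 (permutation p = 1e-05, the smallest that 100000 permutations can give). Spearman rho was 0.89 (permutation p = 2e-05), and r was 0.89 without the 2 most distant animals. In the young batch r was 0.96 (permutation p = 1e-05) and in the aged batch 0.67 (permutation p = 0.00607). The group means were taken out first, so a position that differed between parity groups in both regions was not tested. The deeper libraries do not account for the lower level in young mothers, since at least 105% of the young difference was kept without libraries above 35 M counts (SE 17% in dorsal and 18.7% in ventral libraries). RNA of other cells carried along in varying amount would hold the genes in 1 ratio, and the highest SD of a log2 ratio between 2 of the 4 genes was 0.29, while their mean level ranged from 1.36 to 6.45 log2 CPM between libraries, which is consistent with a single source, but also with joint regulation of the 4 genes. The parity of the young animals, and any difference in handling that went with it, stay open and untested, and the pattern is a hypothesis found and tested on the same data. Young mothers were killed 30 days and aged mothers more than 6 months after birth, so age and time since birth cannot be told apart in it.

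The third pattern is the 369 genes between young biparous and primiparous dorsal libraries. With the number of genes detected as a covariate, their median log2 fold change in the original direction went from 0.32 (median SE 0.08) to 0.24 (median SE 0.09), 76.7% of its value. No gene passed, since the difference shrank and its error grew. All 369 kept their direction, which was likely in advance, because they were picked from the same libraries. Without animals 55, 61 and 68 the median kept 80.2% of its value, and with the 11 libraries under 35 M counts it was 0.30 (median SE 0.09), 93.6% of its value, and again no gene passed. The 76.7% and the 93.6% lie above the bound of 75% that was set beforehand to argue against these causes, and by that bound alone both would be ruled out, but it had to be passed by more than the spread, whose measure was chosen after the values were seen and changed once. By a jackknife over the 15 animals the SE is 10.6% for the covariate (72.4% to 83% without 1 animal) and 19.6% for the depth limit (80% to 106%), so less 1 SE the first falls below the bound and the second falls just below it, while both exceed by more than their SE the 50% below which either would have counted as the cause; a part played by few genes or by depth stays open, as does parity.

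In the regroupings of the same animals, 7 of the 22 counts were each reached by 1 split, the real one. For region, age by region and aged against young this argues against chance, with no allowance made for the 22 counts examined. For region, where labels were exchanged within animals (25 splits), the real counts were 7657 over all animals, 6408 in the young and 7178 in the aged, and the highest of the others were 0, 0 and 456. For age by region, the real count was 3256 and the highest of the others 47 (25 splits). For aged against young, they were 5211 and 16 in the dorsal and 8468 and 3310 in the ventral hippocampus (100 splits). The splits do not separate age from batch. For young dorsal biparous against primiparous animals, the real count was 369 and the highest of the others 218 (100 splits). Chance is not excluded for this count, which fell to 0 without animal 13, 26, 55, 68 or 71. Single splits of other groups of this size also gave more genes than 369. A difference between groups was itself tested and passed in 2 comparisons, the regional difference between ages in 3256 genes and the regional difference between young parity groups in 3 genes.

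Chance cannot be excluded for 3 further counts. For parity by region in the young, 2 of 25 splits gave at least the real 3 genes, with 8 as the highest of the others. For biparous against nulliparous young animals, 9 of 100 splits in the dorsal and 10 of 100 in the ventral hippocampus gave at least the real 1 gene, with 3 and 9 as the highest of the others. For the other comparisons the real count was 0, which any split reaches (25 of 25 or 100 of 100), so the splits say nothing about chance there. The highest of the others were 0 for parity by region in the aged, 1 and 3 for age by parity in the dorsal and ventral hippocampus, 2 and 4 for primiparous against nulliparous and 1 for ventral biparous against primiparous young animals. In the aged animals they were 1 and 2 for primiparous against nulliparous, 3 and 1666 for biparous against nulliparous and 1267 and 0 for biparous against primiparous, dorsal before ventral. The 1666 and the 1267 each came from a single split. Whether they reflect some structure among the aged samples was not tested.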

How the results depend on the processing

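Among the settings below, leaving out the 3 animals with the fewest genes, the covariate and the depth limit were chosen after seeing the data. The counts for region and aged against young stayed within 1.5 times under RLE size factors, without the low-count filter, with DESeq2 and without any 1 animal, and those for region also without the replicate block. RLE size factors moved no share of higher genes by over 10 percentage points and no median log2 fold change of all genes by over 0.1. The gene list tests and the choroid plexus covariate were not run. Without the replicate block, age by region fell from 3256 to 1588 genes (18.1% higher, against 39.6%), 1587 of them shared with the blocked fit, and parity by region in the young from 3 to 0. The block changed no other count by over 1.5 times. With nulliparous animals only, 10 libraries in place of 30, aged against young gave 2032 dorsal and 5148 ventral genes, and ENSRNOG00000058105 and ENSRNOG00000029886 turned to -0.179 and -0.126 in the dorsal hippocampus.

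DESeq2 called 23 genes for parity by region in the young, 2 and 5 for age by parity in the dorsal and ventral hippocampus, and in the young 176 (primiparous against nulliparous), 6 (biparous against nulliparous) and 1203 (biparous against primiparous) in the dorsal and 7 and 9 (each against nulliparous) in the ventral hippocampus. The 1203 were 55.4% higher, against 72.4%, and 348 were shared with edgeR. A single fit over all libraries gave 18, 34 and 999 in young dorsal and 6 and 6 in young ventral libraries, with 50.5% of the 999 higher. Without animals 55, 61 and 68, parity by region in the young and biparous against nulliparous and against primiparous in young dorsal libraries gave 0 genes. With the covariate biparous against primiparous gave 0, and under 35 M counts this and biparous against nulliparous gave 0. The cause was not tested, except that leaving out animals and the depth limit use fewer samples, and that with the covariate the median fold shrank and its error grew.

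Without 1 animal, counts ran from 0 to 6 (without 55) for parity by region in the young, 0 to 3 (without 26) and 0 to 4 (without 26) for age by parity in the dorsal and ventral hippocampus, and in young dorsal libraries 0 to 17 (without 54) for primiparous against nulliparous, 0 to 2 for biparous against nulliparous and 0 to 1334 for biparous against primiparous. In young ventral libraries they ran from 0 to 1 (without 61) and 0 to 2 against nulliparous. In the aged animals every parity count stayed at 0 under every alternative run. For the named genes, 1606 of 1736 values kept their side of the threshold and, where the test gives one, their direction. Of the rest, 98 no longer passed, 30 now passed and 2 turned. Leaving out 1 animal gave 1440 of the 1736 values. Many of these genes did not pass in the main test, so that staying on that side was likely in advance. In simulated counts for primiparous against nulliparous animals, at the real depths and 5 against 5 animals, 60% to 74% of genes changed 1.5-fold and 82% to 86% of genes changed 2-fold were recovered. Depth, group size and the number of changed genes were not varied in them.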

Other observations

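A number of genes marked the individual animal in both regions. For 87 of 14689 genes the deviation from the group mean correlated over the 30 animals between the dorsal and ventral library with r above 0.9, and in 20 shuffles of animals within age the highest such count was 0. ENSRNOG00000029386 and ENSRNOG00000006365 had the highest values (r = 0.99 for both), with log2 CPM values from -3.17 to 4.44 and from -3.82 to 4.34 over the libraries. No explanation was tested for them.

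In exact two-sided permutation tests of the mean of the 4 genes described with the tests of age by parity, the young primiparous and biparous animals differed from the nulliparous animals by -2.46 and -2.53 log2 in dorsal and by -2.76 and -2.64 in ventral libraries (p = 0.00794 each, 0.0238 after Benjamini-Hochberg adjustment over 12 comparisons, 5 animals against 5). In the aged animals the corresponding differences were 0.17 and 0.13 in dorsal and 0.11 and -0.19 in ventral libraries (adjusted p from 0.305 to 0.836). The genes were picked from these libraries, so the p-values describe the pattern and are not independent evidence of it.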
